A study of Homo sapiens with 10 samples.

How the data were processed

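Total RNA from the bone marrow of patients with acute myeloid leukaemia was hybridised to 1-colour Agilent whole human genome arrays with the dye Cy3, and each of 10 arrays held one marrow sample. Per the labels, each marrow held over 80% blasts, the immature leukaemic cells. The sample titles place 5 arrays in a group with a high and 5 in a group with a low peripheral white blood cell count. The titles also carry the word B-cell, which the rest of the labels, on acute myeloid leukaemia and whole marrow, do not use, so the word was not used for grouping.

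The deposited scanner files hold spot intensity values on a linear scale. Per the file headers they were made with Agilent Feature Extraction 10.2.1.3 and had not been normalized between arrays. The columns used were the mean spot intensity, the median local background, the processed signal (the software's own background-subtracted intensity, an alternative here) and the spot flags. The authors also deposited a parameter file for a preprocessing package. It names the mean foreground and median background columns, a background method that sets low differences to 0.5, an offset of 50, quantile normalization and filters at 75% for flags of signal, saturation and outliers. Those settings were followed here in limma 3.58.1 under R 4.3.3, with tables handled in version 1.17.8 of the package data.table, Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 and plots drawn in matplotlib 3.10.9. The original package was not run.

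In that scheme the background is subtracted from the spot intensity and 50 is added before log2. The offset steadies dim probes and shrinks their fold changes, so differences of dim genes are understated. Quantile normalization gives every array the same distribution over its 43376 non-control spots. It cannot show a shift common to most genes, and it leaves the brightest probes little room to differ. Spots marked as outliers were left out and spots of a probe were averaged. A probe was tested when at least 75% of the replicates of at least 1 group were well above background, found, unsaturated, free of outlier flags and above the mean plus 1.5 SD of the negative controls. The parameter file does not say how the 75% limit runs over groups or how the negative-control limit is set, so both are readings made here. Probes of XIST, TSIX and Y-linked genes, 140 in all, were removed before any fit. Of 41000 probes, 24794 were named through a RefSeq accession, 2533 by a current symbol and 869 through an older symbol. The other 12804 kept the name in the file, and genes known only by an accession or clone name are counted but not named. The probe of highest mean log2 signal stood for each gene, which left 23927 genes from 32304 probes. Probe positions are those of the files, on the human build hg18. No genome or annotation of that build was used here, so the exon or untranslated region behind a probe is not given.

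Before samples were averaged, the arrays of each group were compared in pairs on 17825 probes with 1 spot each. The spread of 264 repeated probes within an array gave the noise of a spot. In the low-count group 2 arrays differed by a robust SD of 0.133 on the log2 scale, under their spot noise of 0.184, with a Pearson correlation of 0.997 across probes. The other pairs differed by 0.558 to 1.01, with correlations of 0.855 to 0.933. The 2 arrays were averaged and counted as 1 sample, so the comparison has 5 high-count and 4 low-count replicates. The design fixed before the data were examined had taken all 10 arrays as separate samples, and that fit is kept as an alternative.

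Differences are low minus high white count, from limma's linear model with moderated variance, adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Gene lists fixed before the data were examined, 39 in number and covering marrow cell types and pathways, hold 785 genes, of which 774 are on the array. They were tested with limma's camera, which compares a list with all other genes, using the correlation between members estimated per list. Camera with a preset correlation of 0.01, fry and a two-sided exact permutation test of the list mean per replicate were alternatives. With 5 and 4 replicates there are 126 assignments, and the smallest permutation p is 0.00794. A list mean is the mean over members of log2 value minus the gene's mean. Member counts are given over all genes and adjusted over the list alone.

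The named genes follow a rule fixed before the data were examined. They are, among called genes with a gene symbol, the 12 of largest positive and the 12 of largest negative difference, up to 4 members of smallest p in each list discussed, and CD34, KIT, FLT3, MPO, CD33, CD14, CXCR4, MKI67 and HOXA9. A gene named outside the rule is said to be. A few genes that the rule covers are not reported, so the text names 11 of the 12 genes of largest positive difference and in some lists fewer than 4 members. They stay in the fits, the counts and the list means.

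The arrays came from 3 slides, and each slide was scanned in a run of its own. One slide held 2 high-count replicates and the averaged low-count pair, a second 3 low-count and the third 3 high-count replicates. Slide was therefore tested as a fixed block, as a random block and within the shared slide. Other alternatives were the processed signal scaled to its 75th percentile, normexp background correction with either scaling, no background correction, median centring, other filters and probe rules, array weights, a trended variance, a plain test without moderation, a replicate block and leaving out each replicate. The arrays had 78.9% to 83.6% of spots well above background, a median spot intensity of 118 to 244 and a median background of 22 to 25.5 units. Spots flagged as non-uniform numbered 344 and 61 for high-count replicates 5 and 4, and at most 18 on the other arrays. Both replicates lie on the slide with high-count replicates alone. Among the named genes ADGRE5, ANXA2 and FLT3 had no value in high-count replicate 5. The spike-in variation was 7.74% for high-count replicate 3 and 2.91% to 5.11% on the other arrays. No spot was saturated. The number of arrays limits the precision.

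The fit was tested on simulated data for the comparison of low against high white count over 23689 genes, with the real means and spreads and 200 changed genes per run. It recovered 25.0% of genes changed 2-fold, 70.4% of those changed 4-fold, 86.0% of those changed 8-fold and 95.4% of those changed 16-fold. False calls were 4.95% of all calls. The simulated noise was drawn for each gene on its own and held no slide effect. That rate may therefore not hold for noise shared between genes or tied to slide. In 20 runs with the residuals shuffled between replicates and no group difference, camera called 0 lists per run with the estimated correlation and 11.2 per run with the preset one.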

Results

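Gene expression was measured in bone marrow from patients with acute myeloid leukaemia, a cancer of immature myeloid blood cells, selected for over 80% blasts. The comparison asks how leukaemia that presents with a low white blood cell count in peripheral blood differs from leukaemia that presents with a high count. The 5 high-count arrays each counted as a replicate. In the low-count group 2 of the 5 arrays differed by less than the noise of repeated spots and were counted as 1 sample, which left 4 replicates. The labels describe each array as a marrow sample and each group as 5 patients, so the replicates are taken as separate patients. The sample titles say B-cell although the series describes acute myeloid leukaemia. Markers of B cells are therefore reported with the other cell types. Both groups carry the word, so a difference between the groups cannot tell which cells the samples held, and some levels are given too.

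Red cell genes were higher in marrow from patients with a low white count, and VCAN, CRIP1 and TREM1 were among the genes that were lower. Of 23927 genes tested, 361 passed an adjusted p of 0.05 in limma's moderated test, 263 of them higher and 98 lower with a low count. Among these, 124 were at least 4-fold higher and 44 at least 4-fold lower, and 271 carry a gene symbol. Selenium-binding protein gene SELENBP1 was 37.2-fold higher (log2 difference 5.22 ± 0.38, SE, 5 high and 4 low replicates, adjusted p = 0.000332). ALAS2, whose product starts haem synthesis in red cell precursors, was 29.1-fold higher (4.86 ± 0.43, adjusted p = 0.000995). The probe for SELENBP1 lies on chromosome 1 from 149603471 to 149603530 in hg18 coordinates. Slide was largely tied to group, and a fit with slide as a fixed block rests on the shared slide, with 2 high-count replicates and 1 low-count replicate. In that fit 1 gene passed in limma, SNCAIP, named after its value was seen (log2 difference 5.63, adjusted p = 0.0244), which was not among the 361, and 2041 genes had an unadjusted p under 0.05. The median size of the difference over the 361 genes went from 1.89 to 1.62, while its median SE went from 0.30 to 0.52. All 361 kept their direction within the shared slide, whose arrays were also part of the full comparison, and 347 kept at least 50% of their difference.

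The 11 genes reported among those with a symbol and the largest positive differences include these, and the others were 27.6-fold to 34.3-fold higher. They included the Rh-associated glycoprotein gene RHAG (4.92 ± 0.49), the Kell-associated membrane protein gene XK (4.98 ± 0.54), and the red cell membrane skeleton gene EPB42 (4.79 ± 0.39). TMCC2 (5.10), YPEL4 (5.08), TRIM10 (4.88) and the keratin gene KRT1 (4.81) were also among them. RHCE (4.97) and the fetal globin gene HBG1 (4.83) complete the group. Both have a near-identical neighbour, RHD and HBG2, whose transcripts the probes may share, so the source of their signal is uncertain. These folds are those of the brightest probe of each gene. Other probes gave smaller differences for SELENBP1 (3.32), TMCC2 (2.91), YPEL4 (2.56) and TRIM10 (1.07 and 2.22), and those of ALAS2 (4.85) and HBG1 (4.83) were close to the reported ones. The adjusted p-values of these 11 genes lay between 0.000332 and 0.00354. In each of the 11 every low-count replicate was above every high-count replicate. The genes were chosen by their differences in the same data, so this is not separate support.

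**Figure D1:**
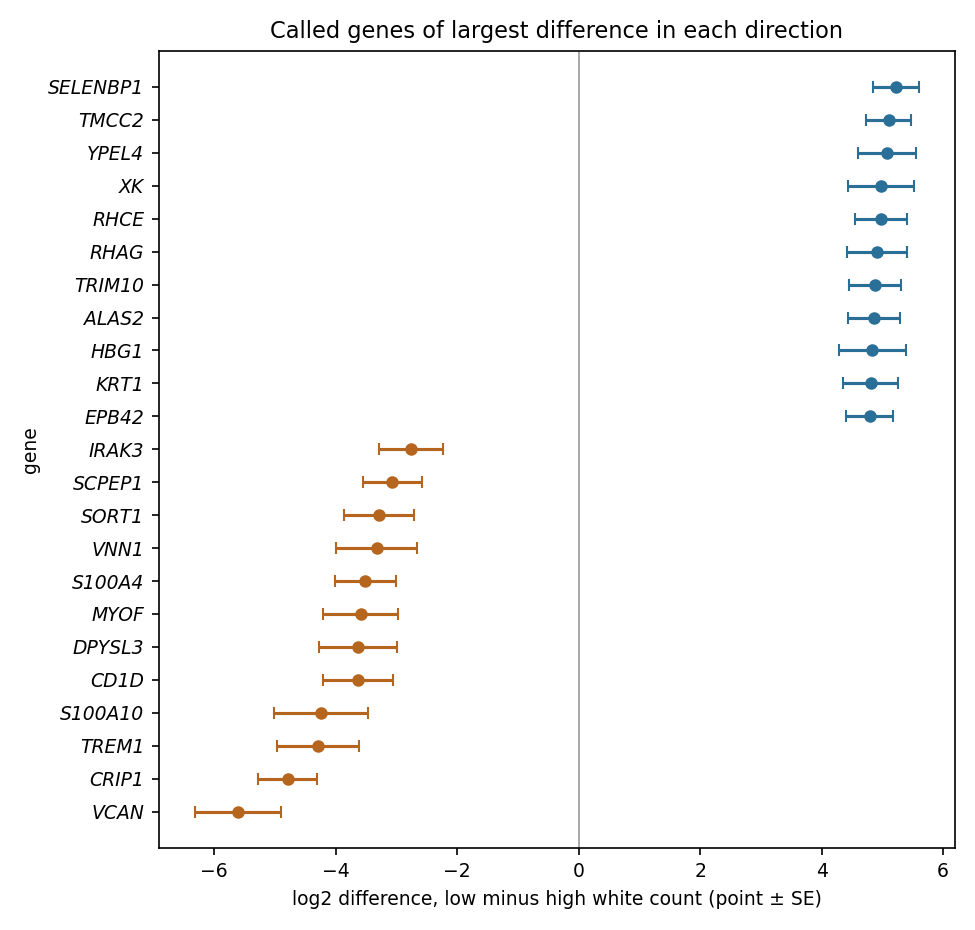
Log2 difference, low minus high white count, for called genes with a symbol and the largest differences, 11 higher and 12 lower (points, bars ± SE from limma, 5 high-count and 4 low-count replicates). The higher genes lie between 4.79 and 5.22 and the lower genes between -5.61 and -2.76.

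The largest negative difference among called genes was that of VCAN, which encodes the matrix proteoglycan versican made by monocytes. It was 48.9-fold lower with a low count (log2 difference -5.61 ± 0.70, SE, 5 high and 4 low replicates, adjusted p = 0.00570). CRIP1, a LIM-domain protein gene, was 27.7-fold lower (-4.79 ± 0.49, adjusted p = 0.00235). TREM1, an activating receptor of monocytes and neutrophils, was 19.5-fold lower (-4.29 ± 0.68, adjusted p = 0.0201). The calcium-binding protein genes S100A10 (-4.24) and S100A4 (-3.51) and the lipid antigen-presenting molecule gene CD1D (-3.63) also fell. So did DPYSL3 (-3.63), the membrane repair gene MYOF (-3.59), the pantetheinase gene VNN1 (-3.32), the sorting receptor gene SORT1 (-3.28), SCPEP1 (-3.07) and IRAK3 (-2.76), an inhibitor of Toll-like receptor signalling. S100A10 differed by -2.51, S100A4 by -5.32 and DPYSL3 by -1.43 within the shared slide, and the second probe of DPYSL3 differed by -0.63. Other probes gave -2.51 for CD1D, -3.33 and -1.30 for MYOF, -3.01 for VNN1 and -2.24 for SORT1. The adjusted p-values of these 12 genes lay between 0.00235 and 0.0478. The probe for VCAN lies on chromosome 5 from 82912058 to 82912117, and that for CRIP1 on chromosome 14 from 105025745 to 105025886.

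Of the 39 gene lists, the erythroid list differed most between the groups. Of its 24 tested members 21 rose with a low count, and 23 rose when adjusted over the list alone. SELENBP1, the haematopoietic nuclear protein gene HEMGN (4.41 ± 0.32) and the anion exchanger gene SLC4A1 (4.55 ± 0.33) were among those of smallest p. The 3 members that did not pass over all genes, named after their values were seen, were GATA1 (2.84, adjusted p = 0.0757), CA2 (3.02, adjusted p = 0.0995) and HBB (0.19, adjusted p = 0.709). HBB lay among the brightest probes in both groups, at 18.4 and 18.6 log2 units, where quantile normalization leaves little room for a difference. The list mean was 2.10 ± 0.31 (SD, n = 4) with a low and -1.68 ± 0.55 (SD, n = 5) with a high count. It was higher in all 4 low-count replicates than in any high-count replicate (difference 3.78, exact permutation p = 0.00794, the smallest possible). Camera gave an adjusted p = 0.0712 with an estimated correlation of 0.364 between members, so the list did not pass the threshold. Within the shared slide the difference was 3.50.

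**Figure D2:**
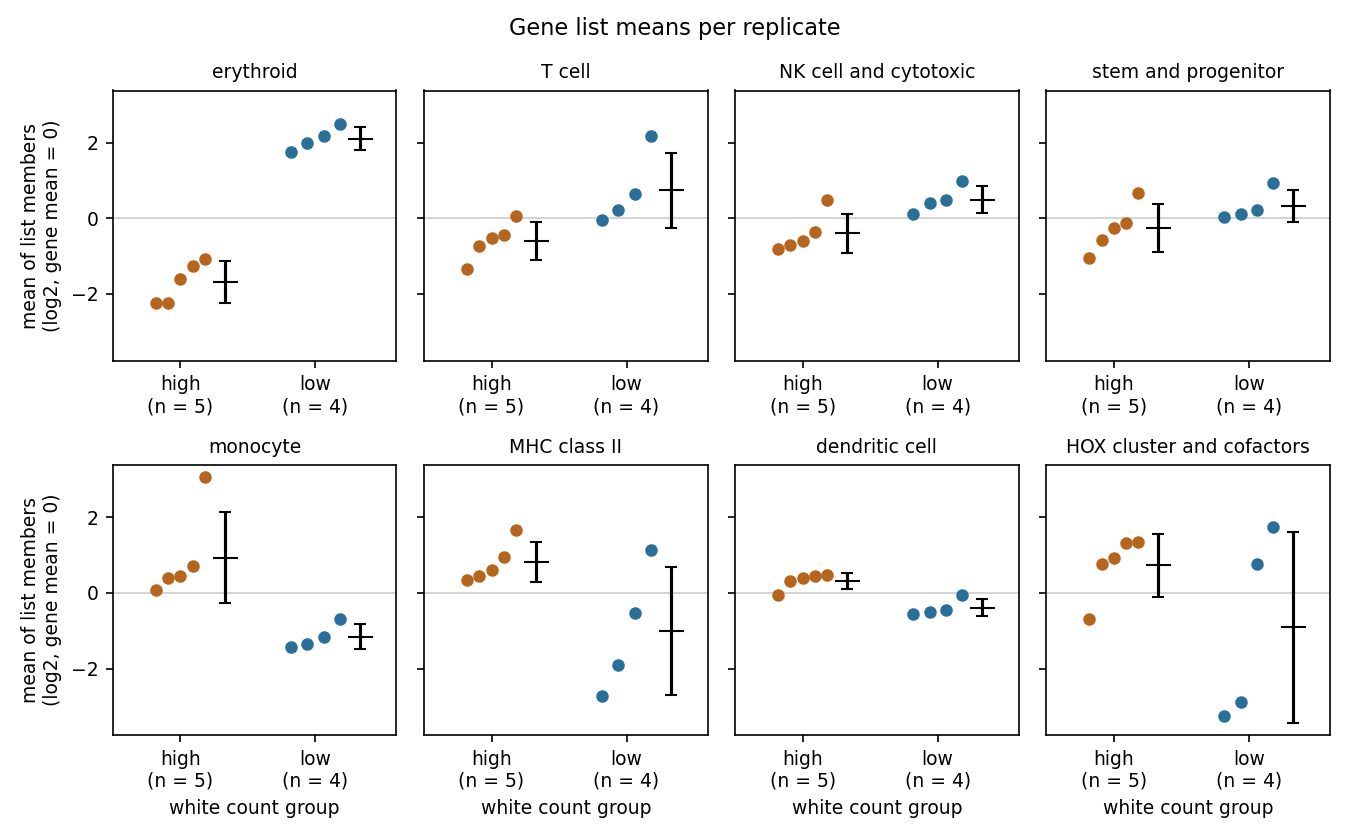
Mean log2 value of list members, centred on each gene's mean, for 8 gene lists (points are replicates in order of value, bars the group mean ± SD). Erythroid means lay above 0 in all 4 low-count and below 0 in all 5 high-count replicates, while HOX means overlapped between the groups.

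None of the 39 lists passed camera with an estimated correlation, and 2 had an unadjusted p under 0.05, the erythroid and the dendritic cell lists. Fry, which asks whether members move one way on balance, called the same pair of lists. The preset correlation called 13 lists and the exact permutation test called 0 after adjustment. Fry's mixed test, which asks whether members change in either direction, called 17 lists. The lists called with the preset correlation were the erythroid, monocyte, dendritic cell, MHC class II, T cell, NK cell, adhesion, protease, NF-kB, complement, oxidative phosphorylation, cholesterol and HOX lists. None of these calls held with the estimated correlation, whose adjusted p is given for each of them.

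All 27 tested monocyte genes had lower means with a low count, and 1 of them, VCAN, passed over all genes. Adjusted over the list alone 6 fell. The integrin genes ITGAM (-2.23, adjusted p = 0.0922) and ITGAX (-2.25, adjusted p = 0.0644) and the transcription factor gene KLF4 (-3.15, adjusted p = 0.0741) did not pass over all genes. The list mean was -1.16 ± 0.33 (SD, n = 4) with a low and 0.93 ± 1.21 (SD, n = 5) with a high count, a difference of -2.09 with all 4 low-count replicates below every high-count replicate (exact permutation p = 0.00794, adjusted p = 0.133). Camera's adjusted p was 0.476 with an estimated correlation and 1.98e-10 with the preset one. Within the shared slide the difference was -3.31, and without high-count replicate 2, which lies on that slide, the full difference was -1.56.

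Genes of dendritic cells and of antigen presentation also had lower means. In the dendritic cell list 9 of 12 members were lower and 1 passed, the interleukin-3 receptor gene IL3RA (-1.46 ± 0.25, adjusted p = 0.0301), which leukaemic blasts also express. Adjusted over the list alone 3 fell. LILRA4 (-2.45), a marker of plasmacytoid dendritic cells, BATF3 (-1.43) and CLEC10A (-2.12) did not pass over all genes. The dendritic list mean differed by -0.71 (camera adjusted p = 0.306 with an estimated correlation, fry adjusted p = 0.0199) and by -0.99 within the shared slide. In the MHC class II list 10 of 11 members were lower, none passed over all genes and 1 fell when adjusted over the list alone, the lysosomal reductase gene IFI30 (-4.17 ± 0.90, adjusted p = 0.0622 over all genes). HLA-DPA1 (-2.38), CD74 (-1.94) and CTSS (-1.44) had adjusted p-values of 0.242, 0.290 and 0.290. That list mean differed by -1.81 (exact permutation p = 0.0635, camera adjusted p = 0.554 with an estimated correlation) and by -3.51 within the shared slide.

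Markers of T and NK cells had higher means with a low count, but the groups overlapped: 3 of 4 low-count replicates for T cells and 1 of 4 for NK cells lay above every high-count replicate. All 20 tested T cell genes had positive differences, 1 passed over all genes and 7 rose when adjusted over the list alone. The passing gene was TRAT1, a partner of the T cell receptor (3.27 ± 0.59, adjusted p = 0.0326). UBASH3A (1.26) and CD247 (1.32) did not pass over all genes. The T cell list mean differed by 1.34 (exact permutation p = 0.0238, camera adjusted p = 0.488 with an estimated correlation of 0.652), by 0.87 without low-count replicate 2 and by 0.53 within the shared slide. Of 18 NK and cytotoxic genes 2 rose, the pore-forming protein gene PRF1 (1.65 ± 0.29) and the chemokine gene XCL1 (1.05 ± 0.19, adjusted p = 0.0326). KLRD1 (0.89) and KLRF1 (1.35) did not pass over all genes, and 9 members rose when adjusted over the list alone. PRF1 differed by 1.06 and KLRF1 by 0.56 within the shared slide. The NK list mean differed by 0.88 (exact permutation p = 0.0476, camera adjusted p = 0.476 with an estimated correlation) and by 0.69 within the shared slide. None of the 19 B cell genes passed, and their mean differed by 0.19 with -0.22 within the shared slide. Of these genes, named outside the rule, MS4A1 was at 6.78 and 7.10 log2 units with a high and a low count. PAX5 was at 7.16 and 7.44 and CD79A at 10.8 and 11.7, while the primary granule gene MPO was at 16.1 in both groups. No plasma cell gene (mean 0.73), mast cell or basophil gene (1.24), megakaryocyte gene (0.50) or lymphoid precursor gene (0.85) passed. Within the shared slide these differences were 0.84, 2.21, -0.36 and 0.10.

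Markers of leukaemic immaturity did not move together. In the stem and progenitor list 1 of 17 members rose, TAL1 (2.96 ± 0.43, adjusted p = 0.0126, other probe 1.43), a transcription factor gene that erythroid precursors also use. ERG (1.62), THY1 (0.83) and BAALC (0.57) did not pass, and the list mean differed by 0.59 (0.28 within the shared slide). CD34 (1.39 ± 2.17) varied within groups by more than it differed and was well above background in 3 of the 4 low-count replicates. KIT (2.28 ± 1.06, adjusted p = 0.332) did not pass. In the 17-gene leukaemia stem cell score 1 of 16 tested members fell, DPYSL3 (-1.43 within the shared slide), and AKR1C3 (1.61), CDK6 (1.11) and NYNRIN (-1.29) did not pass. The score's list mean differed by -0.11 (-0.39 within the shared slide). FLT3 differed by 0.15 ± 0.91, with a sign that changed with the scaling, MPO by -0.07 ± 1.17 and CD33 by -1.74 ± 0.94. CXCR4 (0.47 ± 0.76), MKI67 (0.37 ± 0.41) and CD14 (-2.02 ± 1.31) did not pass either. CD33 differed by -0.52 without low-count replicate 2 and CD14 by -0.87 without high-count replicate 2, and within the shared slide they differed by -0.86 and -4.46. Over the fits that left out a replicate, CXCR4 ranged from 0.17 without low-count replicate 2 to 1.15 without high-count replicate 5, and MKI67 from 0.08 without high-count replicate 2 to 0.58 without high-count replicate 3. No proliferation gene of 34 (mean 0.36), primary granule gene of 14 (-0.54) or neutrophil gene of 22 (0.71) passed. Within the shared slide these means were 0.71, 0.55 and 0.19.

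Among HOX genes and cofactors, 17 of 18 tested members had lower means with a low count and none of these passed. HOXA9 (-3.48 ± 1.74), HOXA7 (-3.19 ± 1.54), HOXB5 (-3.12 ± 1.31) and HOXA10 (-2.22 ± 1.03) had adjusted p-values of 0.291 to 0.369. In the low-count group HOXA9, HOXA7 and HOXB5 were well above background in 3 of 4 replicates and HOXA10 in 2. The group was split, with HOXA9 at 5.98 and 6.74 log2 units in replicates 1 and 2 and at 13.1 and 14.8 in replicates 3 and 4. Its high-count mean was 13.6. In low-count replicates 1 to 4 the mean of the list was -3.25, -2.89, 0.76 and 1.74. The list mean was -0.91 ± 2.53 (SD, n = 4) with a low and 0.73 ± 0.83 (SD, n = 5) with a high count. Its difference of -1.64 (exact permutation p = 0.262, camera adjusted p = 0.735 with an estimated correlation of 0.724) turned to 0.63 within the shared slide. The low-count replicate on that slide is replicate 4. The full difference was -0.86, -0.98 and -2.52 without low-count replicates 1, 2 and 4. HOXA3 was the only member called (0.82 ± 0.16, adjusted p = 0.0436), but its second probe differed by -1.78, so its direction is not settled.

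Several other lists held 1 to 3 called members. The erythropoietin receptor gene EPOR rose by 2.40 ± 0.26 (adjusted p = 0.00309, other probes 0.30 and 2.26) in the cytokine receptor list. The GM-CSF receptor gene CSF2RA (-2.20 ± 0.39, adjusted p = 0.0308) and IL3RA fell there, IFNGR1 (-1.35) did not pass, and the list mean differed by -0.31. SLC2A1, which encodes the glucose transporter of red cells and other cells, rose by 3.28 ± 0.40 (adjusted p = 0.00524). It was the 1 called gene of 24 in the hypoxia and glycolysis list, whose mean differed by -0.12 and in which ENO1 (-0.72), TPI1 (-0.62) and P4HA1 (-0.81) did not pass. In the BCL2 family BCL2L1, which protects red cell precursors from cell death, rose by 2.12 ± 0.19 (adjusted p = 0.00122, other probe 0.98) and BNIP3L, which acts in clearing mitochondria from maturing red cells, rose by 1.48 ± 0.24. BCL2 (1.98) and BBC3 (0.44) did not pass, and the mean of the 17 members differed by 0.24. The efflux pump gene ABCG2 rose by 2.29 ± 0.28 (adjusted p = 0.00524) in the drug transport list. ABCB1 (0.91), ABCC5 (1.25) and MVP (-1.54) did not pass over all genes there, 3 members rose and 1 fell when adjusted over the list alone, and the list mean differed by 0.10. Within the shared slide the means of these lists differed by -0.51, -0.42, 0.26 and -0.05, in the order given.

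Leukocyte adhesion, protease, NF-kB, complement and metabolic genes had lower list means with a low count. Of 27 adhesion genes 1 fell, the integrin gene ITGB7 (-1.90 ± 0.33, adjusted p = 0.0304), while ADGRE5 (-2.37, adjusted p = 0.0556) did not pass over all genes. Adjusted over the list alone 4 fell. The adhesion list mean differed by -0.52 (-0.79 within the shared slide, camera adjusted p = 0.476 with an estimated correlation). None of the 24 matrix protease and inhibitor genes passed over all genes, and 2 fell when adjusted over the list alone. TIMP2 (-1.74), ADAM17 (-1.32), MMP19 (-1.48) and ADAM10 (-0.79) had the smallest p-values. That list mean differed by -0.64, with all 4 low-count replicates below every high-count replicate (-1.15 within the shared slide, -0.43 without high-count replicate 2, camera adjusted p = 0.476 with an estimated correlation). None of 21 NF-kB targets passed, among them TNFAIP2 (-2.21), TNFAIP3 (-1.81), IER3 (-2.10) and NFKB1 (-1.15). Their mean differed by -0.89 (-1.71 within the shared slide, camera adjusted p = 0.554 with an estimated correlation). Of 18 complement and coagulation genes CFP, which encodes properdin, fell by 2.65 (SE 0.53, adjusted p = 0.0455), while ANXA2 (-2.69), THBD (-1.98) and CD59 (2.03) did not pass over all genes. Adjusted over the list alone 1 rose and 2 fell. That mean differed by -0.97 (camera adjusted p = 0.476 with an estimated correlation) and by -0.62 without high-count replicate 2. The value within the shared slide, -1.35, includes that replicate.

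In the oxidative phosphorylation list COX5B, a subunit of cytochrome c oxidase, fell by 1.03 (SE 0.17, adjusted p = 0.0227), the 1 called gene of 32. UQCRC1 (-0.59), NDUFA1 (-0.74) and UQCRQ (-0.60) did not pass. The list mean differed by -0.20 (-0.27 within the shared slide, camera adjusted p = 0.676 with an estimated correlation). No cholesterol synthesis gene of 18 passed over all genes, and 1 fell when adjusted over the list alone. CYP51A1 (-1.53), STARD4 (-1.04) and SREBF2 (-0.98) did not pass. The mean of these genes differed by -0.54 (-0.95 within the shared slide, -0.35 without low-count replicate 4, camera adjusted p = 0.672 with an estimated correlation).

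No member of the other lists passed over all genes, and adjusted over the list alone 1 chemoattractant receptor rose and 1 fell, 1 angiogenesis gene rose, and 1 p53 target rose and 2 fell. Chemoattractant receptors differed by -0.52 on average, immediate early genes by -0.50, inflammatory cytokines by -0.42 and unfolded protein response genes by -0.24, and within the shared slide by -1.50, -0.47, -0.81 and -0.36. Without high-count replicate 2, which lies on that slide, chemoattractant receptors differed by -0.18 and immediate early genes by -0.28. Ribosomal proteins differed by -0.09, MYC targets and ribosome biogenesis genes by 0.06 and angiogenesis genes by -0.05, and the sign of the last 2 of these changed with the scaling. Within the shared slide these means differed by 0.21, 0.34 and -0.20. The type I interferon response differed by 0.59 with an SD of 2.10 among the low-count replicates, and by -1.04 within the shared slide. In 4 lists the median, the mean and camera's direction differed in sign. These were the p53 targets (median -0.08, mean 0.10), heat shock genes (0.13, -0.06), chemokines (0.19, -0.19) and stroma and endothelium (-0.03, 0.14). Their means within the shared slide differed by -0.12, -0.30, -0.87 and -0.08. The full difference of the chemokines was -0.025 without high-count replicate 2.

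**Figure D3:**
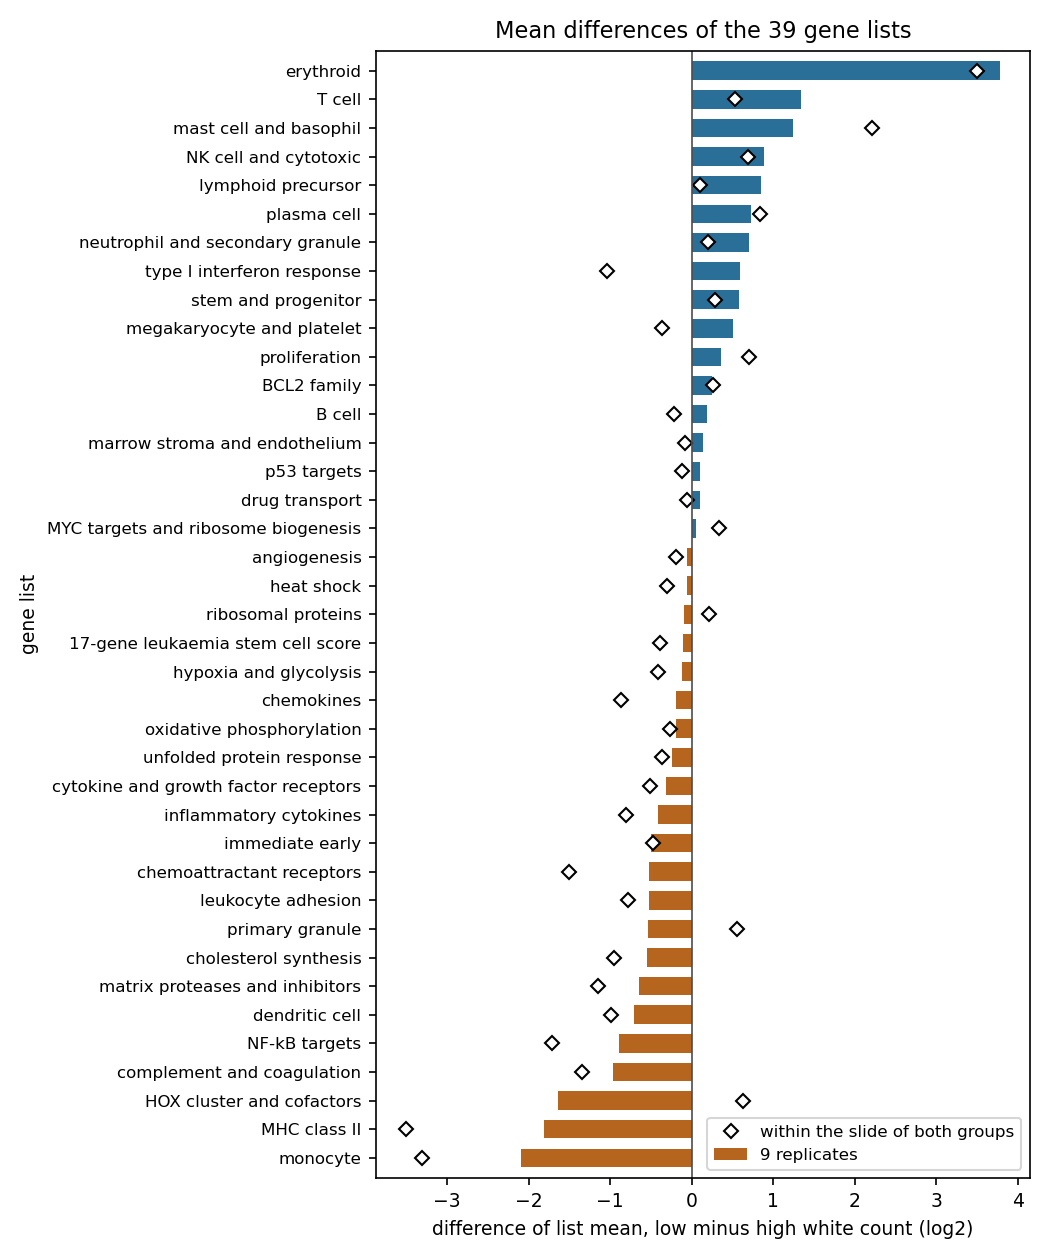
Difference of list mean, low minus high white count, for the 39 gene lists (bars, 5 high-count and 4 low-count replicates on the log2 scale) and the same difference within the slide that held both groups (diamonds). The erythroid difference of 3.78 was 3.50 within that slide, and the HOX difference of -1.64 was 0.63 there.

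The groups did not overlap for 1669 of 23927 genes (6.98%), against 1.59% given by chance on average over arrangements. Genes vary together, and the spread of that share between arrangements was not measured. The groups also largely follow slide, so the share does not tell white count from slide. Other probes were tested for 124 of the called genes, and for 104 of these every other probe had the same sign. When a replicate was left out, 154 to 303 genes were called. The count was lowest without low-count replicate 2 (154) and was 162, 188, 172, 239 and 178 without high-count replicates 1 to 5. Among the genes named above, CFP lost its call in all 9 of these fits, HOXA3, IL3RA, TRAT1, XCL1, SORT1 and VNN1 in 8, and DPYSL3 and ITGB7 in 7. BNIP3L, CSF2RA, PRF1, IRAK3 and S100A10 lost it in 6, MYOF in 5, CD1D and COX5B in 3 and SCPEP1 in 2, and none of these genes changed direction there. Leaving out 1 replicate moved the mean difference of 29 of the 39 lists by over 1.5 times or turned it. The other 10 were the erythroid, monocyte, dendritic cell, NK cell, MHC class II, stem and progenitor, adhesion, NF-kB, unfolded protein response and oxidative phosphorylation lists.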

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

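The tests of the gene counts, by shared slide and by splits of the samples, were written before their results were seen, and the other tests below were chosen only afterwards.

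In 13 of 276 groups of values one replicate stood far from the rest, measured as its gap to the nearest other replicate over the whole range of its group. Chance gives about 1 in 20 groups, and 13 is 4.71% of those examined. Among list means the highest replicate stood apart for monocyte genes in the high-count group (0.791 of the range), megakaryocyte genes (0.854) and NF-kB targets (0.854) in the low-count group, and complement and coagulation genes in the high-count group (0.7101). Among genes the highest replicate stood apart for BCL2L1 (0.880) and THBD (0.798) in the high-count group and for CLEC10A (0.868) and MYOF (0.867) in the low-count group. The lowest stood apart for CD33 (0.906) and HBG1 (0.873) in the low-count group and for HOXA7 (0.7495), ITGAX (0.772) and ITGB7 (0.726) in the high-count group.

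The count of 361 called genes was weighed against slide and against a chance arrangement of the samples. Of 62 genes called between the slides that held 1 group each, 96.8% kept their direction within the third slide, which took no part in that call, against 58.5% of all genes. The direction thus held in samples outside that call. That slide holds 2 high-count replicates and 1 low-count replicate, and genes that vary together are not separate checks, so slide cannot be ruled out. A fit with slide as a block called 1 gene, with a median SE over the 361 genes of 0.52 against 0.30. The count is unlikely to come from a chance arrangement of the samples. Of 100 splits of the 9 replicates into 5 and 4, drawn from 126, only the real one (1 of 100) gave as many genes. The highest other split gave 64. The real split also largely follows slide, so its rank does not tell white count from slide. What the 2 groups of patients differ in besides the white count is not given in the labels and stays open.

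The higher erythroid genes were weighed against slide, scaling and a lower blast share. Their list mean differed by 4.06 when arrays were scaled to the 75th percentile, so the choice between these scalings does not account for it. Within the shared slide it differed by 3.50 (3.23 between its closest replicates of opposite groups). That slide holds 2 high-count replicates and 1 low-count replicate, which are also part of the full difference, so slide cannot be ruled out. A lower blast share alone would raise markers of other cell types alike. The erythroid list rose by 2.44 more than the T cell list, the highest of the other types set against it (exact permutation p = 0.0159). The T cell genes TRAT1, UBASH3A and CD247 had means of 6.80, 6.64 and 8.21 log2 units with a high count. The offset understates differences of such dim genes. Alternatives outside the fits that left out a replicate included the processed signal, to which no offset was added. Over these the T cell list mean rose by at most 1.81 and the erythroid list mean by at least 3.50. The offset alone thus does not account for the gap. Signal over background still limits dim T cell genes, so the comparison cannot decide and a lower blast share stays open. A larger share of red cell precursors in the low-count marrow and red cell gene expression in the blasts both stay open, since whole-marrow RNA does not say which cells it came from. HBB was among the brightest transcripts in both groups (18.4 and 18.6 log2 units).

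The lower monocyte genes were weighed in the same way. Their list mean differed by -3.31 within the shared slide (-2.14 between its closest replicates of opposite groups) and by -2.42 with the 75th percentile scaling. Dilution of all myeloid transcripts alike by erythroid RNA would lower progenitor genes too. The monocyte list fell by 2.35 more on the log2 scale, a difference of -2.35, than 14 stem and progenitor genes other than TAL1, KIT and GATA2, which themselves differed by 0.26 (exact permutation p = 0.0159). Against primary granule genes the difference was -1.56 (exact permutation p = 0.206), so a fall shared with those genes stays open, as does a more monocytic leukaemia in the high-count group.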

How the results depend on the processing

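The planned design took all 10 arrays as separate samples. That fit became an alternative, and the replicate block on it and the filter at 50% of replicates were chosen, after seeing the data. The called genes numbered 361 and kept their direction, as far as they were tested, in all settings but the filter on every array, where 336 of 337 did, the mean of a gene's probes, where 357 of 361 did, and the fit without low-count replicate 3, where 360 did. The count was 231 with normexp and the 75th percentile, a scaling that moved the median of all genes by 0.13, and 242 with the processed signal at the 75th percentile. It was 596 with array weights, 852 with slide as a random block (correlation -0.130), 145 with a plain two-sample test and 741 with all 10 arrays as separate samples. With slide as a fixed block it was 1, with a median SE over the 361 genes of 0.52 against 0.30, and the lowest adjusted p of an erythroid gene was 0.104. Median centring called 281 genes, 57.3% of them higher against 72.9%, and the fit on 10 arrays 62.1%. The processed signal at the 75th percentile went the other way, with 194 genes higher and 48 lower (80.2% higher). Every probe on its own gave 437 called probes of 32304, which is not a count of genes. The other settings on the same replicates gave 297 to 381 genes. Leaving out a replicate gave 154 to 303 genes: 162, 188, 172, 239 and 178 without high-count replicates 1 to 5, 154 without low-count replicate 2, and 282 to 303 without the others. Fewer samples were tested there. The number of lists passing was 13 with the preset correlation, 2 with fry and 1, the erythroid list, with every probe on its own or all 10 arrays (adjusted p 0.0457 and 0.0433). The adjusted p of that list ran from 3.61e-38 with the preset correlation to 0.453 with the replicate block on all 10 arrays. With fry's mixed test, which counts changes in either direction, it was 17. In the other settings in which lists were tested it was 0, and they were not tested with the random block or the plain test. The cause of these changes was not tested. The 23 genes named for the largest changes had no change of direction in 391 values outside the fits that left out a replicate, and lost their call in 42 of these and in 45 of 207 that left one out. Some of these settings, such as the plain test and the trended variance, keep each difference as it is and could not change a direction. HOX genes such as HOXA9 and the gene CD34 lay near background in some low-count replicates and far above it in others. In low-count replicates 1 to 4 HOXA9 was at 5.98, 6.74, 13.1 and 14.8 log2 units. CD34 was at 14.8, 14.5, 6.38 and 6.07 there. Signal over background limits the values near background.

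The replicate numbers of the labels did not pair the samples. Same-numbered samples had correlations of -0.129, 0.102, -0.096, -0.054 and -0.048 between their deviations from the group means, and 0 of 5 correlated best with their own number. The replicate block over all 10 arrays called 171 genes and 0 lists. On the 9 replicates the block was not run, since the averaged pair carries 2 numbers.

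Results that changed sign were small or varied within groups, apart from HOXA3, whose probes disagree (-0.48 with their mean). FLT3 was -0.041 with the 75th percentile of the processed signal and -0.037 with normexp and the 75th percentile, -0.12 with median centring, -0.25 with array weights and -0.025 with the random block. The means of angiogenesis and MYC target genes were 0.034 and -0.0013 with the processed signal at the 75th percentile, and 0.079 and -0.016 with normexp and that scaling. MYC targets were -0.12 with median centring. Every probe on its own gave 0.018 for heat shock and -0.081 for p53 targets. The mean of probes gave 0.018 for angiogenesis, 0.011 for heat shock and -0.058 for the BCL2 family. Array weights gave -0.0066 for MKI67 and 0.31 for MPO. Slide as a fixed block gave -1.75 for CD34, 0.21 for HOXA10, 0.056 for HOXA7, 0.85 for HOXA9 and 1.16 for MPO. It gave list means of 0.63 for HOX, 0.55 for primary granule, -0.36 for megakaryocyte, -0.22 for B cell, -0.078 for stroma, -1.04 for interferon response, 0.21 for ribosomal proteins, -0.12 for p53 targets and -0.052 for drug transport. All 10 arrays gave 0.25 for MPO, with or without the replicate block. Leaving out a replicate gave ranges of -0.061 to 2.85 for CD34, -0.40 to 0.65 for FLT3 and -0.70 to 1.37 for MPO. For list means it gave -0.38 to 0.16 for the 17-gene score, -0.24 to 0.84 for megakaryocyte, -0.018 to 0.60 for proliferation, -0.12 to 0.024 for angiogenesis, -0.45 to 1.03 for interferon response, -0.81 to 0.052 for immediate early, -0.15 to 0.10 for heat shock, -0.13 to 0.19 for MYC targets and -0.0083 to 0.22 for p53 targets. The cause was not tested.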

Other observations

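The lists, tests and genes in this part were chosen after the values of the erythroid and S100 genes had been seen. Of 14 genes for enzymes and carriers of haem synthesis 7 rose with a low count. These included ALAS2 and FECH, which the erythroid list already held, the mitochondrial iron importer gene SLC25A37 (log2 difference 2.63, adjusted p = 0.00941), ABCB6 (2.97) and PPOX (1.51). All 14 had positive differences, with a mean of 1.85, and TMEM14C (0.06) had the smallest. Of 13 erythroid transcription factors and receptors 5 rose, among them GFI1B (3.68, adjusted p = 0.00527), KLF1 (2.39, adjusted p = 0.00853) and NFE2 (1.26, adjusted p = 0.0436). LMO2 (0.17) and MYB (0.77), which blasts also express, did not pass, and STAT5A differed by -0.55.

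The hypothesis that the erythroid difference extends to other genes was tested on the members that no fixed list holds. The 12 such haem synthesis genes had a mean difference of 1.501, and 5 of them rose. The 9 such transcription factors and receptors had a mean difference of 0.92, and 2 of them rose. Both means had an exact permutation p of 0.00794, the smallest that 126 assignments can give. Genes of the same cells are not independent evidence for the erythroid difference or its source, and most of these members did not pass on their own.

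Of 18 tested genes of the S100 calcium-binding family, 3 fell with a low count, S100A4, S100A10 and S100A6 (-2.02, adjusted p = 0.0135). The monocyte genes S100A8 (-1.36), S100A9 (-1.72) and S100A12 (-0.73) did not pass, and 14 of the 18 had negative differences. Other called genes that fell were the intermediate filament gene VIM (-2.28, adjusted p = 0.00808), the actin-binding protein genes CFL1 (-1.53, adjusted p = 0.00751) and GSN (-2.05, adjusted p = 0.0332), and the pyruvate kinase gene PKM (-1.34, adjusted p = 0.00631). The gene of smallest p among those that rose was ERFE, the gene of the iron-regulating hormone erythroferrone made by red cell precursors (4.32, adjusted p = 0.000263).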
